A study of Danio rerio with 2 samples.

How the data were processed

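Cells of a mutant and a sibling group of zebrafish embryos were compared, each measured in 1 library, so the group and the library cannot be told apart. Per the labels' protocols, embryos of an incross of tnnt2a carriers were dissociated at 48 hpf, kdrl:EGFP-positive cells were sorted by flow cytometry, and each sample was run on its own lane with a 10x Chromium 3′ kit. Mutant embryos were told by a heart that did not beat, per the series' design text, and wild-type and heterozygous siblings stayed pooled. Both libraries carry the same batch number in the labels. The number of embryos in each pool is not given in the sources used here.

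The deposited values are whole-number counts per gene and cell barcode in a matrix for each library, per the file headers, taken as UMI counts from the kit named in the labels' protocols. STARsolo, Scanpy and the genome build danRer11 are named per the submitters' processing notes, and their versions, the gene annotation and the rule that called cells are not given in the sources used here. The matrices held 32057 genes each and no barcode below 4620 UMIs in the mutant and 4871 in the sibling library, so barcodes of low depth and empty droplets were not analysed here. Gene symbols came from the deposited gene tables.

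Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, which removed 2 and 132 mutant and 1 and 54 sibling barcodes. Scrublet, as run by scanpy 1.11.5 within each library with an expected doublet rate of 0.06, called 130 of 6792 mutant cells (1.91%) and 70 of 5494 sibling cells (1.27%), which were removed. Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes, ranked within each library, were chosen without the members of the endocardial, valve, flow, venous, lymphatic, arterial and tip lists. Both libraries were clustered jointly on 30 principal components and 15 neighbours, with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), which gave 29 clusters. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

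The filters, the clustering settings, the 24 marker sets besides general endothelial markers, the 21 gene lists and the rule for named genes were set before the data were examined. Of the marker and list symbols, 15 were absent from the annotation and 6 were held more than once and left out. A cluster was named for the class whose markers had the highest mean log2 fold over all other cells, if that was at least 0.8 and at least 0.5 above the next class. At least 3 markers had to be seen in 10% of its cells, and at least 1 had to be among its top 10 genes by fold, counting genes seen in 25% of its cells, with no other class holding more there. These thresholds were set after the clusters had been seen. Clusters of an endothelial class, and unnamed clusters with cdh5 in 50% of cells, counted as endothelial-like. Cluster 27, with skeletal muscle markers and cdh5 in 85.7% of cells, stayed outside and held 0.390% of mutant and 0.0369% of sibling kept cells.

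The planned comparison of endocardial-like cells could not be made with 1 such cell in the mutant library. Cluster 5, which scored highest for veno-lymphatic and next for endocardial markers, took its place for the list medians, the slope and the named genes, and this was decided after the data were seen. UMIs were summed per library over the cells of a set and divided by the set's total as CPM. Folds are mutant over sibling, with exact Poisson intervals for CPM, exact conditional binomial intervals for ratios and Clopper-Pearson intervals for shares, all at 95% and for counting error only. A fold against 0 UMIs was computed against a floor of 3 UMIs over the group's sum. Log2 folds for lists and slopes had 0.5 UMI added to each sum. A list member was measured with at least 20 UMIs over both libraries, and counted as higher or lower with a fold of at least 1.5 and an interval excluding 1, before any subtraction of the median gene. List medians carry intervals from 1000 Poisson draws and a percentile among 10000 random lists matched in 20 bins of mean expression.

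Named genes had at least 100 UMIs over both libraries and 20 CPM in either, without mitochondrial, ribosomal protein, haemoglobin and code-named genes and markers of other cell types. They were ranked by the interval bound of the ratio nearest 1, and the first 12 in each direction were named in cluster 5 and the first 5 elsewhere. A gene that met this rule in some sets is not reported here. For each list up to 4 members of at least 50 UMIs with the largest folds were eligible as examples. Tnnt2a, kdrl, nfatc1, klf2a, prox1a, flt4, lyve1b, stab2 and mrc1a were reported regardless. Genes of the profile plot, snai2, gata5 and other genes given for cells with a UMI were chosen after their values were seen. For shares of cells with a UMI, each cell was thinned to 4500 UMIs.

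The slope was fitted across genes of at least 50 UMIs, with an interval from 200 Poisson draws. The steps that give folds, lists and named genes were tested on simulated data for cluster 5, with 200 of 3447 genes changed by 2-fold or 4-fold. Intervals held the true value for 94 to 96.1% of genes. The rule for higher and lower members took 98% of genes changed by 2-fold, 100% of those changed by 4-fold and 0.862% of 3247 unchanged genes, and all 24 genes named were truly changed. Counts were drawn as Poisson from a shared profile, so the simulation covers counting error only. Clumping of UMIs in few cells and differences between libraries were not simulated.

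Alternatives kept doublets, required 1000 genes and at most 5% mitochondrial UMIs, changed the resolution to 0.5 or 2, kept list genes among the variable genes, or clustered each library on its own. Others used the edgeR 4.0.16 TMM or DESeq2 1.42.0 median-of-ratios scalings (R 4.3.3), totals without technical genes, cells thinned to 2000 UMIs, the mean of each cell's CPM, minimums of 100 UMIs or none, 5 UMIs added, or only cells of at least 2000 UMIs, which left out no cell. Alternatives added after seeing the data left out the 2291 genes at least 2-fold apart in the endocardial-like cluster, centred each library before clustering, counted unnamed clusters that scored highest for endocardial markers, and left list genes out of the slope. Sets of cells outside the endothelium, the split of cluster 5 by lyve1b and the tests of explanations were also chosen after the data were seen. No p-value was computed, since cells of 1 library are not replicates. Genes without a symbol of their own were left out of naming.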

Results

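Gene expression was measured in single cells sorted for kdrl:EGFP, a transgene active in endothelial and endocardial cells, from zebrafish embryos at 48 hpf. The embryos came from crosses of carriers of the tc300b allele of tnnt2a, the gene for cardiac troponin T, without which the heart does not beat. The tnnt2a mutant library held cells of homozygous embryos, and the sibling library held cells of wild-type and heterozygous embryos together. There was 1 library per group, so no difference between genotypes has a replicate check and no test between genotypes was possible. Intervals are at 95%, exact for CPM, shares and ratios and from Poisson draws for list medians and slopes, and cover counting error only. The mutant library held 6925 cell barcodes and 81021440 UMIs, with a median of 9417 UMIs and 1840 genes per barcode. The sibling library held 5549 barcodes and 82963361 UMIs, with a median of 12693 UMIs and 2363 genes. After filtering, 6662 mutant and 5424 sibling cells were kept, of which 3156 and 2674 were endothelial-like.

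The targeted gene, tnnt2a (ENSDARG00000020610), was nearly undetected in the mutant library. In all kept cells it had 5 UMIs in the mutant library, 1 each in 5 cells, and 1308 UMIs in the sibling library. In endothelial-like cells it had 1 UMI in the mutant library (0.0393 CPM) and 1217 in the sibling library (48.2 CPM), a ratio of 0.000815 (2.06e-05 to 0.00455). Of the sibling UMIs, 1149 lay in endocardial-like cells (307.5 CPM, 290 to 326), where myl7, a cardiomyocyte myosin light chain, had 5 UMIs (1.34 CPM). The mutant library held 1 endocardial-like cell, so most of this difference lay in cells that it lacked. The ratio therefore does not show a loss of transcript within cells. Outside the endocardial-like cells, 1 mutant and 68 sibling UMIs remained in the endothelium. A 3′ tag reads the level of the transcript, not the mutation itself.

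The series asks how contraction of the heart bears on the identity of the endocardium, the inner lining of the heart, and on veno-lymphatic endothelium. Endocardial-like cells made up 15.6% of the sibling endothelial-like cells (418 of 2674, 14.3 to 17.1%). In the mutant library 1 of 3156 endothelial-like cells was endocardial-like (0.0317%, 0.000802 to 0.176%). Top genes of the endocardial-like cluster included tnnt2a, the mutated gene, which was not kept out of the variable genes. Its own part in the clustering was not tested. The cluster was also led by f8 and clic2, by hand2 and gata5, transcription factors of the heart field, and by has2, which makes the hyaluronan of the cardiac jelly. It held cells of nearly 1 library alone, so its genes and its size cannot be separated, and clustering without the 2291 genes that set it apart gave no endocardial-like cluster. Other filters and clusterings gave 0 to 0.911% in the mutant and 4.58 to 17.2% in the sibling library. The share also depends on the EGFP sort, on the cell totals at which barcodes were called (lowest 4620 and 4871 UMIs) and on depth, with endothelial-like cells at a median of 6917 mutant and 8144.5 sibling UMIs.

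Counts of cells with a UMI do not depend on clusters within the endothelium. Hand2 was seen in 0.317% of mutant and 10.4% of sibling endothelial-like cells, and in 0.190% and 7.07% after each cell was thinned to 4500 UMIs, which left out no cell. Gata5 was seen in 1.68% and 10.6% (1.24% and 8.08% thinned). Has2 was seen in 2.503% and 8.68% (1.68% and 5.61% thinned), with 0 of 1014 mutant and 0.214% of sibling neutrophil-like cells as background. In neutrophil-like cells, at medians of 15562.5 mutant and 20480.0 sibling UMIs, hand2 was seen in 0 of 1014 mutant cells (up to 0.363%) and in 0.321% of sibling cells. Gata5 was seen there in 0.0986% and 0.321%, so the mutant endothelial share of gata5 lay above the background and that of hand2 lay close to it. Coagulation factor gene f8 was in 5.86% of mutant and 21.35% of sibling endothelial-like cells (4.59% and 19.1% thinned). After thinning it was also in 7.495% of mutant and 9.08% of sibling neutrophil-like cells, but in 0.422% of mutant veno-lymphatic-like, 0.444% of mutant arterial-like and 31.3% of mutant cluster 5 cells.

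Arterial-like cells, those of cluster 7, made up 14.3% of mutant (13.1 to 15.5%) and 6.69% of sibling (5.78 to 7.71%) endothelial-like cells. Cluster 6 scored higher for arterial markers (2.21 against 1.31) but stayed unnamed, since its score for tip markers was 2.15. The top genes of cluster 7 included vim and slc29a1b, which were higher over the whole mutant endothelium, so its share may in part reflect the library. Veno-lymphatic-like cells made up 37.5% (35.8 to 39.2%) and 32.8% (31.0 to 34.6%). Cluster 5, led by lyve1a, edn2 and bmp6, made up 11.4% (10.3 to 12.6%) and 11.1% (9.94 to 12.4%). Brain endothelial-like cells were at 10.4% and 9.95%, cycling cells of cluster 3 at 13.5% and 15.1%, and cluster 6, led by aqp8a.1, esm1 and apln, at 12.8% and 8.75%. Without the endocardial-like cells the sibling shares were 7.93% for arterial-like, 38.9% for veno-lymphatic-like and 13.2% for cluster 5 cells. Counted with cluster 5, veno-lymphatic-like cells made up 48.95% of mutant and 43.9% of sibling endothelial-like cells, endocardial-like cells included in the total. Without those, both parts were smaller in the mutant (37.5% and 11.4%) than in the sibling library (38.9% and 13.2%), with overlapping intervals. Top genes of cluster 5 held lyve1a but also bmp6, hapln1b and fn1a of the endocardial list. In sibling cluster 5 against sibling endocardial-like cells, bmp6 was at 276 and 22.2 CPM, fn1a at 402 and 328 CPM and hapln1b at 332 and 451 CPM. Without cluster 5, the veno-lymphatic-like class joined 3 clusters. Cluster 0 held 747 mutant and 646 sibling cells, cluster 10 held 422 and 30, and cluster 17 held 15 and 201, so clusters 10 and 17 may each be a library and not a cell type.

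**Figure D1:**
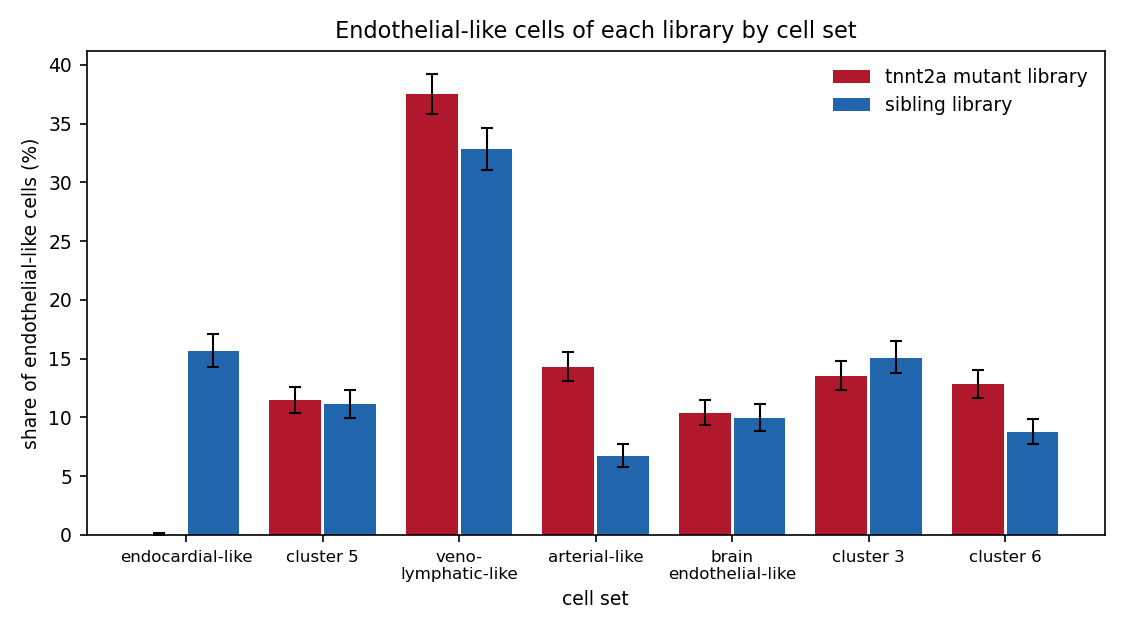
Share of endothelial-like cells (percent, vertical axis) in 7 sets of cells for each library, 1 library per genotype, with bars for exact 95% binomial intervals. Endocardial-like cells stood at 15.6% in the sibling and 0.0317% in the mutant library, and arterial-like cells at 6.69% and 14.3%.

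Over all endothelial-like cells (25433803 mutant and 25226030 sibling UMIs, 3.28% and 2.15% of them mitochondrial), genes of the endocardium and heart field were lower in the mutant library. Hand2 stood at 0.393 CPM against 28.3 CPM, 72.0-fold lower (38.9 to 151). F8 was 12.1-fold lower (14.4 and 174 CPM, 10.9 to 13.5), anxa2a, an annexin, 18.2-fold lower (11.2 and 204 CPM, 16.2 to 20.6) and the collagen gene col5a2a 13.8-fold lower (1.46 and 20.02 CPM, 9.85 to 19.8). The intermediate filament gene vim was 11.2-fold higher (350.7 and 31.2 CPM, 10.5 to 12.1). Also higher were the sterol synthesis enzyme cyp51 at 5.21-fold (22.1 and 4.24 CPM, 4.23 to 6.47), the nucleoside transporter slc29a1b at 4.37-fold, tm4sf18 at 3.02-fold and dhrs3a at 2.92-fold. Prox1a, the lymphatic transcription factor, was 1.88-fold lower (9.87 and 18.5 CPM, 1.61 to 2.196). Klf2a, a transcription factor induced by flow, stood at 60.75 and 91.18 CPM, and nfatc1, an endocardial transcription factor, at 9.99 and 21.0 CPM. Kdrl was at 691 and 777 CPM, flt4 at 191 and 163, lyve1b at 384 and 375, stab2 at 222 and 299.8 and mrc1a at 104 and 124 CPM.

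In the list of endocardial identity, 13 of 16 measured members were lower by at least 1.5-fold with an interval excluding 1, and 0 were higher. Gata5 was 11.8-fold lower (2.63 and 31.0 CPM) and the tetraspanin cd151 16.1-fold lower. In the valve list 10 of 14 were lower and 1 was higher, with the proteoglycan vcana at 2 and 168 UMIs (ratio 0.0118, 0.00142 to 0.0433) and wnt9b at 3 and 75 UMIs (ratio 0.0397). In the flow list 9 of 17 were lower and 1 higher, with the calcium channel trpv4 10.8-fold lower, id2b 5.29-fold lower and ackr3b 2.16-fold higher. Heart-field genes were lower for 7 of 10 members, including gata6 at 3.62-fold and tbx20 at 3.45-fold. Proliferation genes were lower for 14 of 22, including mcm5 at 2.22-fold and tyms at 2.09-fold. Arterial genes were higher for 4 of 17 and lower for 1, with hey2 1.69-fold and cxcr4a 1.76-fold higher and unc5b 11.7-fold lower. Hypoxia and glycolysis genes were split, with 6 higher, 5 lower and 10 neither, eno1a being 2.52-fold higher and epas1b 2.48-fold lower. Of 21 lymphatic genes 1 was higher and 5 lower, with osr2 3.79-fold higher and cdh6 2.35-fold lower. Of 15 venous genes 0 were higher and 2 lower, nr2f2 by 1.68-fold.

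The median gene lay below 0, at −0.26 on the log2 scale in this set, and other scalings moved it by as much (0.26 with TMM and 0.27 with median-of-ratios factors). List medians are therefore given relative to the median gene, with their percentile among 10000 random lists matched on expression, as a description of these libraries. The relative median was −1.26 for endocardial identity, −1.54 for the valve list and −0.88 for heart-field genes, each at percentile 0. It was −0.32 for flow (percentile 0.12), −0.44 for proliferation (percentile 0), 0.39 for arterial genes (percentile 99.9), 0.52 for hypoxia (percentile 100), 0.03 for lymphatic genes (percentile 36.1) and 0.0050 for venous genes (percentile 19.1). The lists share members, so their medians are not separate results. Gata4, gata5, gata6, hand2 and tbx20 count in both the endocardial and the heart-field list. Klf2a, notch1b, wnt9b and id2b count in both the valve and the flow list. Several members are also markers that named the endocardial-like cluster, so the falls of these lists partly restate its near absence. In all, 21 lists were described in 15 sets of cells, so some percentiles near either end would arise by chance.

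Leaving out the endocardial-like cells removed 418 sibling cells and 1 mutant cell, named by markers that are partly members of the endocardial and valve lists. A rise of these lists was therefore largely fixed in advance, and they no longer stood low in the mutant library. In the endocardial list 5 of 16 members stayed lower, with hand2 6.15-fold (3.09 to 13.6), heg1 3.11-fold and the fibronectin gene fn1a 2.29-fold lower, and the relative median was 0.01 (percentile 54.8). Of the valve list 2 members were higher and 0 lower, has2 by 2.58-fold (1.75 to 3.90) and snai2, a factor of endothelial-to-mesenchymal transition, by 1.59-fold, with a relative median of 0.38. Snai2 had only 3 UMIs (0.803 CPM) in sibling endocardial-like cells, against 13.4 CPM in mutant and 6.97 CPM in sibling veno-lymphatic-like cells. Its rise therefore does not speak for valve cells. The flow list was at −0.12 and the lymphatic list at −0.12 (percentile 1.62), with 7 of 21 lymphatic members lower, prox1a by 2.01-fold. Arterial genes were at 0.31 (percentile 99.25), hypoxia genes at 0.49 and proliferation genes at −0.46 (percentile 0).

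Cluster 5 was kept apart from the veno-lymphatic-like class and compared by its number, because endocardial markers scored next after veno-lymphatic markers there (0.584 and 1.19, as mean log2 folds). It stood in place of the endocardial-like comparison, which 1 mutant cell could not give, and this choice was made after the data were seen. In the sibling library its summed UMIs held genes of both classes. Lyve1a was at 784 CPM, against 0.268 in endocardial-like cells, and hapln1b, a hyaluronan link protein, at 332 CPM against 451. Gata5 was at 25.9 CPM against 181.7. Such sums do not show these genes in the same cells. Stab2 was in 82.9% of sibling cells with a lyve1b UMI and in 22.2% of those without (75.9% and 19.4% thinned). F8 went the other way, in 19.9% and 63.0% (11.6% and 56.1% thinned), so the cluster may mix cells of both kinds. F8 was at 136.9 CPM in sibling cluster 5 and 118.5 CPM in mutant cluster 5, far below 1029 CPM in sibling endocardial-like cells. Lyve1a was at 1023 CPM and hapln1b at 467 CPM in mutant cluster 5, though lyve1a lay in fewer of its cells, 36.0% of mutant against 49.5% of sibling cells (35.5% and 46.8% thinned, with 0.986% and 0.321% of thinned neutrophil-like cells as background). The 297 sibling cells had a median of 7125 UMIs and the 361 mutant cells a median of 6413.

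**Figure D2:**
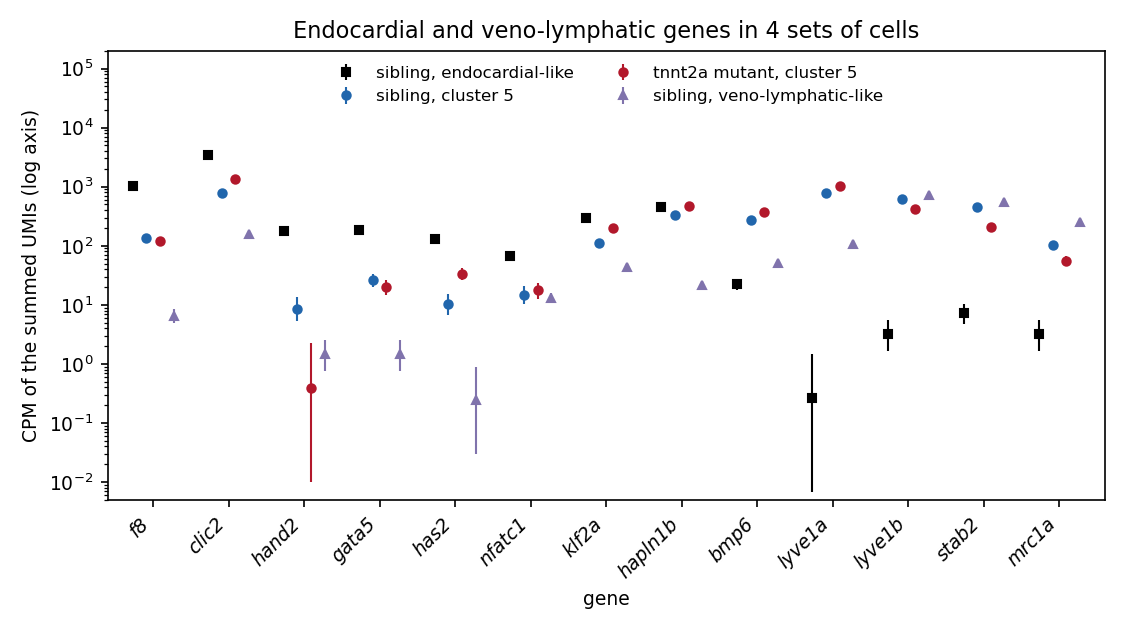
CPM of summed UMIs (log axis) of 13 endocardial and veno-lymphatic genes in sibling endocardial-like, sibling cluster 5, mutant cluster 5 and sibling veno-lymphatic-like cells, 1 library per genotype, with exact 95% Poisson bars. Gata5 stood at 25.9 CPM in sibling and 19.9 CPM in mutant cluster 5 and at 181.7 CPM in sibling endocardial-like cells, and hand2 at 8.64, 0.398 and 177 CPM.

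In cluster 5 (2514141 mutant and 2315722 sibling UMIs), the natriuretic peptide gene nppb, the tip cell genes angpt2a and esm1 and the Notch ligand dll4 were among the genes higher in the mutant library. Nppb had 262 UMIs (104 CPM) against 0 in the sibling library, at least 80.4-fold higher, and lay in 7.20% of mutant cells (6.37% thinned). In sibling cluster 5 it was in 0 of 297 cells (up to 1.23%), and in neutrophil-like cells in 0.197% of mutant and 0 of sibling cells. Angpt2a was 21.9-fold higher (85.1 and 3.89 CPM, 11.3 to 48.6), and esm1 7.27-fold higher (361 and 49.7 CPM, 5.98 to 8.90). Dll4 was 4.09-fold higher (84.7 and 20.7 CPM, 2.98 to 5.71). The chemokine scavenger ackr4b was 14.9-fold higher (8.51 to 28.4), slc29a1b 12.4-fold (7.89 to 20.7), the clotting factor gene f13a1b 5.71-fold (4.08 to 8.19) and plvapb 3.25-fold (2.91 to 3.63). Igfbp1a stood at 3369 and 1143 CPM (2.95-fold higher), id1, a target of BMP signalling, was 2.87-fold higher (2.55 to 3.24), and the insulin signalling adaptor irs2b was at 81.9 and 21.6 CPM (2.77 to 5.28-fold higher).

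Lower in mutant cluster 5 were the transporter abcc2 at 17.3-fold (5.17 and 89.4 CPM, 9.89 to 33.0), the metallothionein mt2 at 11.2-fold (18.3 and 205 CPM, 8.27 to 15.5) and the ammonium transporter rhag at 9.43-fold (19.1 and 180.1 CPM, 6.98 to 12.997). Slc29a1a was 8.82-fold lower (5.80 to 13.9), the laminin receptor bcam 6.46-fold (4.67 to 9.15), kcnn1a 5.69-fold, rbfox3a 5.39-fold, bves 5.10-fold and kif26aa 4.16-fold lower. The interleukin receptor il13ra2 was 3.51-fold lower (2.56 to 4.88), the transcription factor foxp4 3.45-fold lower (2.97 to 4.03) and alkaline phosphatase alpl 3.23-fold lower (2.52 to 4.18). The scavenger and hyaluronan receptor gene stab2 was lower as well, as were mrc1a and lyve1b. Stab2 was 2.196-fold (208 and 456 CPM, 1.98 to 2.44) lower, mrc1a 1.81-fold (56.1 and 101.5 CPM, 1.46 to 2.25) and lyve1b 1.49-fold (418 and 624 CPM, 1.38 to 1.62) lower. Klf2a was 1.83-fold higher (204 and 111 CPM, 1.58 to 2.14) and kdrl 1.40-fold lower (706 and 989.8 CPM). Nfatc1 at 17.5 and 14.7 CPM, flt4 at 109 and 104 CPM and prox1a at 9 and 5 UMIs had intervals that included equality. Tnnt2a had 0 mutant UMIs and 37 sibling UMIs, at least 13.4-fold lower, but all 37 lay in 3 of 297 cells (1.01%, 0.209 to 2.92%), against 0 of 361 mutant cells (up to 1.02%).

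Most valve and flow genes passed in neither direction in mutant cluster 5, where mitochondrial UMIs were 3.12% of mutant and 1.9995% of sibling UMIs. In the valve list 2 of 8 measured members were higher and 0 lower, has2 3.22-fold (33.4 and 10.4 CPM, 2.03 to 5.31) and klf2a, with a relative median of 0.44 (percentile 99.7). Has2 was in 16.3% of mutant and 5.39% of sibling cells (12.2% and 3.03% thinned). In the flow list 3 of 13 were higher and 2 lower, with edn1, the endothelin gene, 1.90-fold higher (162 and 85.1 CPM, 1.60 to 2.27), the chemokine cxcl12a 1.82-fold lower and hspg2 1.87-fold lower, and a relative median of 0.34 (percentile 99.4), or 0.17 (−0.13 to 0.47) before subtraction. In the endocardial list 2 of 15 were higher, 3 lower and 10 neither, with tmem88a 2.40-fold higher, heg1 3.26-fold lower and fn1a 2.07-fold lower, and a relative median of 0.24 (percentile 95.7). Gata5 was in 9.97% of mutant and 10.1% of sibling cells (7.48% and 7.41% thinned), against 55.0% of sibling endocardial-like cells. Without the genes that set the endocardial-like cluster apart, the cells matching cluster 5 made up 11.2% of mutant and 21.0% of sibling endothelial-like cells, and the medians before subtraction of the median gene turned to −0.44 for the endocardial, −0.53 for the valve and −0.29 for the flow list. That match held 560 sibling cells, against 297 in cluster 5, and no endocardial-like cluster remained. Sibling endocardial-like cells may have joined it, so these medians do not speak for cluster 5 itself.

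Most genes of vessel identity also passed in neither direction in mutant cluster 5. Arterial genes were higher for 4 of 11 and lower for 0, with the chemokine receptor cxcr4a 9.95-fold (21.5 and 2.16 CPM, 4.01 to 31.9), aqp8a.1 2.37-fold and aqp1a.1 1.80-fold higher, and a relative median of 0.52 (percentile 99.9). The arterial list was also higher in mutant neutrophil-like cells, so part of this rise may be RNA from other cells, which was not tested. Tip and angiogenic genes were higher for 4 of 11 and lower for 0, including mcamb at 1.504-fold, at 0.36 (percentile 99.0). Lymphatic genes were higher for 1 of 15, angpt2a, and lower for 4, including cdh6 at 2.13-fold and nrp2a, a receptor for VEGFC, at 1.99-fold, at −0.28 (percentile 0.52). Venous genes were higher for 1 of 13, the apelin receptor aplnrb at 1.68-fold, and lower for 4, including ephb4a, the receptor of ephrin B2, at 2.04-fold, at −0.042 (percentile 24.2). Pan-endothelial genes were higher for 1 of 17 and lower for 3, including the angiopoietin receptor tek at 2.23-fold and fli1b at 1.61-fold, at −0.040 (percentile 8.85).

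In the signalling lists, too, most members passed in neither direction in cluster 5. MAPK targets were higher for 4 of 10 and lower for 0, spry4 by 2.51-fold, etv5b by 2.26-fold, etv5a by 2.22-fold and dusp2 by 1.95-fold, with a relative median of 0.51 (percentile 99.95). BMP and TGF-beta genes were higher for 4 of 17 and lower for 1, bambia being 2.46-fold higher and tgfb1a 1.65-fold lower, at 0.42 (percentile 99.98). Notch genes were at 0.43 (percentile 99.9) with 1 of 13 higher, dll4, and lfng at 345 and 449.5 CPM and nrarpa at 130 and 99.8 CPM. Wnt genes split, with 1 of 7 higher and 1 lower, lef1 by 3.18-fold, at −0.07 (percentile 45.7). Of 6 Yap and Taz targets 0 passed in either direction, ccn1 lying at 101 and 76.9 CPM, at 0.22 (percentile 87.8).

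Proliferation genes were lower for 12 of 21 members in mutant cluster 5 and higher for 0, including the replication helicase gene mcm7 at 2.64-fold, top2a at 2.53-fold and tyms at 2.51-fold, with a relative median of −0.62 (percentile 0). Hypoxia and glycolysis genes were higher for 5 of 13 and lower for 1, with eno1a 2.89-fold, ldha 2.05-fold and pgk1 1.78-fold higher, at 0.39 (percentile 99.8). Matrix and cardiac jelly genes were higher for 3 of 26 and lower for 7, with nid1a 2.49-fold higher and the hyaluronidase gene hyal2a 2.62-fold lower, at −0.046 (percentile 31.9). Junction and cytoskeleton genes were higher for 1 of 20, flna at 2.102-fold, and lower for 2, podxl at 2.80-fold and tjp1b at 2.07-fold, at −0.016 (percentile 14.8). Dissociation stress genes were higher for 1 of 22, ier2b at 2.88-fold, and lower for 0, at 0.33 (percentile 99.9), while socs3a was 1.48-fold higher. Heart-field genes were lower for 1 of 7, mef2cb lying at 81.9 and 109 CPM, at −0.21 (percentile 17.7). Immune and interferon genes were lower for 2 of 6, nfkb2 by 1.88-fold, at −0.07 (percentile 46.3). Lipid and scavenger genes were higher for 1 of 17, lipoprotein lipase gene lpl at 2.19-fold, and lower for 4, including apoeb at 1.89-fold, at 0.10 (percentile 68.4). In neutrophil-like cells, which should lack them, 9 of 16 pan-endothelial genes were higher in the mutant library and 0 lower. Relative medians in those cells were 1.02 for pan-endothelial, 1.18 for arterial, 1.101 for lymphatic and 1.72 for endocardial genes, at levels such as 13.7 and 4.26 CPM for clec14a. In cluster 5, markers of other cell types differed as well, with the haemoglobin gene hbbe1.3 at 200 and 107 CPM, pvalb2 at 146 and 95.003 CPM, lyz at 863 and 744 CPM and krt4 at 191 and 236 CPM.

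**Figure D3:**
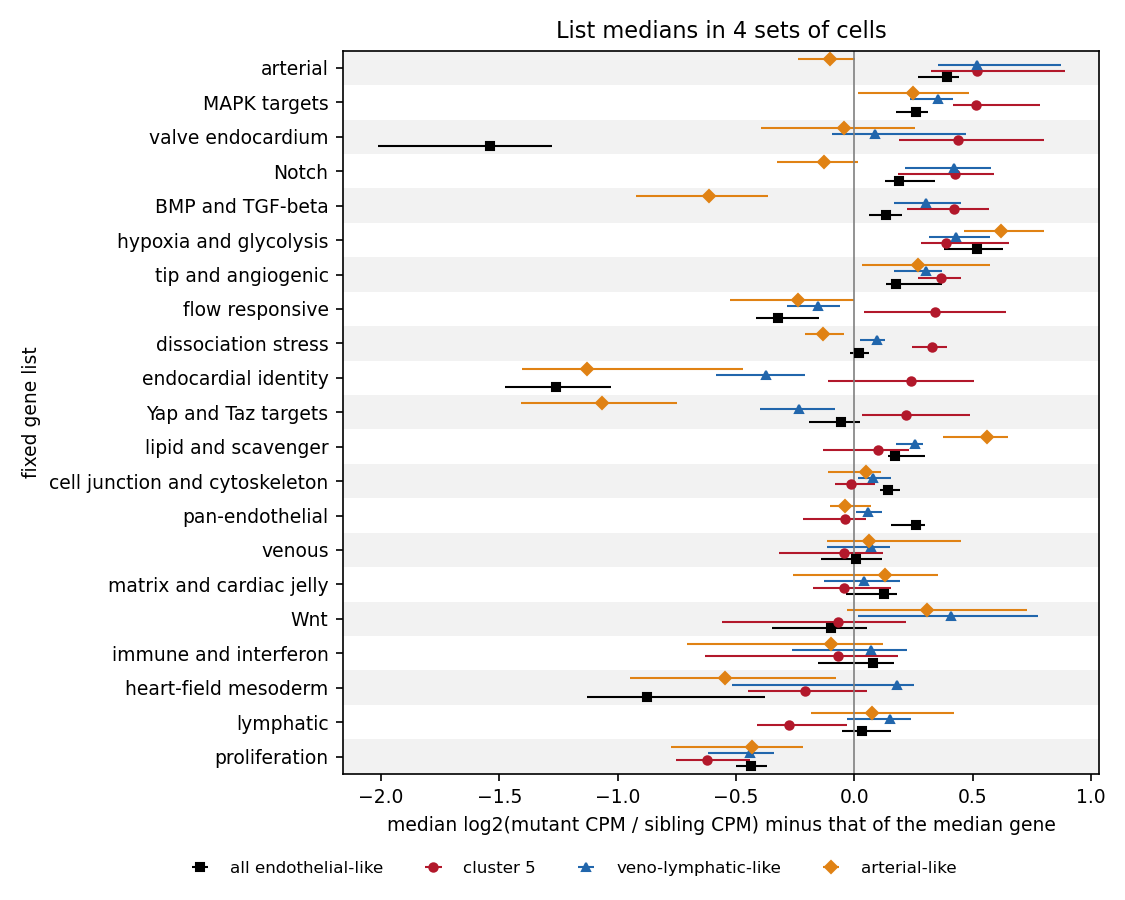
Median log2 ratio of mutant to sibling CPM of each of 21 gene lists, minus the median gene, in all endothelial-like, cluster 5, veno-lymphatic-like and arterial-like cells, 1 library per genotype, with bars for 95% of 1000 Poisson draws. Endocardial identity lay at −1.26 over all endothelial-like cells and at 0.24 in cluster 5, and proliferation genes lay below 0 in all 4 sets.

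A further comparison asked whether the difference between libraries in cluster 5 followed the difference between sibling veno-lymphatic-like and endocardial-like cells. Across 5710 genes the slope was −0.00821 (−0.0149 to −0.00160), with r = −0.0172. Without the list genes it was −0.00254 (−0.00996 to 0.00432) across 5647 genes. Other sets gave slopes from 0.0208 to 0.0919. Genes are not independent replicates, and the slope turned positive when each library was clustered on its own (0.0245) and with no count minimum (0.00355), and fell to −0.0471 at resolution 2 and −0.105 with the stricter filter on cells.

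In veno-lymphatic-like cells, most lymphatic and scavenger genes passed in neither direction. Prox1a was 2.08-fold lower in the mutant library (18.4 and 38.4 CPM, 1.72 to 2.52), cdh6 2.96-fold lower and stab2 1.41-fold lower (397 and 559.5 CPM). Flt4, the VEGFC receptor, stood at 320.5 and 260.1 CPM, lyve1b at 732 and 718 CPM and mrc1a at 193 and 249 CPM. The metallothionein mt2 was 7.80-fold higher (41.0 and 5.26 CPM, 5.68 to 11.0), vim 5.70-fold, btk 4.49-fold, cyp51 4.17-fold and tm4sf18 3.22-fold higher. Lower were efemp2b at 10.1-fold, krt94 at 5.16-fold, alpl at 3.88-fold, slc29a1a at 3.24-fold and the complement gene cfd at 3.14-fold. Kdrl was at 465 and 613 CPM, nfatc1 at 9.27 and 12.96 CPM and klf2a at 39.9 and 44.1 CPM. The class held 1184 mutant and 877 sibling cells, and its values set mutant cells of clusters 0 and 10 against sibling cells of clusters 0 and 17.

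Mitochondrial UMIs were 3.30% of mutant and 2.28% of sibling UMIs in veno-lymphatic-like cells. Arterial genes were higher there for 6 of 15 members and lower for 1, with aqp1a.1 2.37-fold, dll4 2.22-fold and cxcr4a 3.14-fold higher, and a relative median of 0.52 (percentile 99.99). As in cluster 5, RNA from other cells was not tested as a part of this rise. Notch genes were higher for 5 of 16, including the targets hey1 at 6.51-fold and her6 at 2.67-fold, at 0.42 (percentile 99.99). BMP and TGF-beta genes were higher for 5 of 16, id1 by 2.62-fold, at 0.30 (percentile 99.7). Lymphatic genes were higher for 2 of 19 and lower for 3, with osr2 3.41-fold higher, at 0.15 (percentile 89.1). Venous genes passed in 0 of 14 cases, nr2f2 being 1.49-fold lower, at 0.07 (percentile 52.6). Endocardial genes were lower for 5 of 10, at −0.38 (percentile 1.26), and proliferation genes for 12 of 22, mcm5 by 2.22-fold, at −0.44 (percentile 0). Gata6 was at 4.77 and 2.63 CPM in sibling and mutant cells, against 77.1 CPM in sibling endocardial-like cells, while heg1 was at 10.8 and 4.11 against 18.5. RNA or stray cells of the endocardial-like cluster, nearly all sibling, could bear on such levels. This was not tested, and the endocardial list was higher in mutant neutrophil-like cells. Hypoxia genes were higher for 6 of 17, eno1a by 2.48-fold, at 0.43 (percentile 99.98).

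In arterial-like cells (450 mutant and 179 sibling cells) vim was 15.9-fold higher (929.6 and 58.6 CPM, 12.95 to 19.6) and vegfaa, the angiogenic growth factor, 7.86-fold higher. Lyve1a was 7.33-fold, fxyd1 4.46-fold and ap1s3b 3.78-fold higher. Anxa2a was 30.8-fold, cfd 16.1-fold, fstl1a 15.9-fold, rhag 14.0-fold and cyp1a, an enzyme induced by aryl hydrocarbons, 13.6-fold lower. Mitochondrial UMIs were 3.51% of mutant and 2.67% of sibling UMIs there, and dissociation stress genes were lower for 5 of 23, at a relative median of −0.13 (percentile 1.445). BMP and TGF-beta genes were lower for 9 of 16 and higher for 1, including smad6a at 5.20-fold, at a relative median of −0.62 (percentile 0). Yap and Taz targets were lower for 5 of 5, amotl2a by 2.78-fold, at −1.07 (percentile 0.105), and endothelin gene edn1 was 6.22-fold lower. Endocardial genes were lower for 6 of 11, at −1.13 (percentile 0). Anxa2a was at 1164 CPM in sibling endocardial-like cells, which the mutant library nearly lacked. Whether RNA or stray cells of that cluster bear on these genes was not tested. Arterial genes were higher for 2 of 15 and lower for 4, with cxcr4a 2.89-fold higher and aqp8a.1 5.85-fold lower, at −0.10 (percentile 14.4). Lipid and scavenger genes were higher for 4 of 15, mrc1a by 2.26-fold and dab2 by 1.92-fold, at 0.56 (percentile 100), and hypoxia genes higher for 6 of 15, at 0.62 (percentile 100).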

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

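The tests of explanations in this part, with their bounds, were chosen only after the results had been seen, and the bound for regrouped cells was changed after its value was seen.

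A few genes stood in opposite directions in cluster 5 and in another endothelial-like set, and these differences were not tested, with 1 library per group. Angpt2a was higher in mutant cluster 5 (log2 4.38) but lower in arterial-like cells (6.71 and 19.3 CPM), a difference of 5.90 in log2 fold. It was also lower in cluster 6 (79.5 and 309 CPM), where the difference from cluster 5 was 6.34. Irs2b, higher in cluster 5, was at 14.9 and 30.9 CPM in cluster 6, a difference of 2.97. Mt2 was lower in mutant cluster 5 (18.3 and 205 CPM) and higher in mutant veno-lymphatic-like cells (41.0 and 5.26 CPM), a difference of −6.42.

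The near absence of endocardial-like cells from the mutant library, 1 cell against 418, was weighed against technical explanations. After scaling to the depth of the mutant endothelium, 90.2% of sibling endocardial-like cells (86.9 to 92.9%) would still lie above the lowest mutant cell total of 4620 UMIs. That argues against a drop in depth alike for all cells. Mutant endocardial cells with less RNA than other cells cannot be judged this way, since only called cells were used. Over all endothelial-like cells, 156 marker genes outside the lists had a median of −1.01 relative to the median gene (−1.12 to −0.98). Loss of all endocardial-like cells would give −0.91. That argues against regrouping, within the endothelial-like clusters, of mutant endocardial cells that kept most of these genes. The genes were picked from sibling endocardial-like cells, and clusters outside the endothelium were not examined. Exclusion by the sort stays open, since sibling endocardial-like cells had the lowest kdrl level of the endothelial-like sets, 213 CPM against 613 to 1470 CPM, and EGFP itself was not measured. The sort also passed cells outside the endothelium, 52.6% of mutant and 50.7% of sibling kept cells, so the kdrl level alone does not decide this question. A loss of endocardial identity in hearts that do not beat may also underlie the near absence, as may a loss of heart tissue at dissociation. With 1 library per group these remain untested.

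Vim was higher in the mutant library in each of the 13 sets of cells examined, by 15.9-fold in arterial-like, 20.2-fold in brain endothelial-like and 3.85-fold in cluster 5 cells. Free RNA from 1 common source would add a similar amount to every set. The gap between libraries ranged from 4.74 CPM in cluster 2 to 870.9 CPM in arterial-like cells, a ratio of 184, which argues against such RNA as the whole cause. A difference between embryos, or in how the cells were handled, may underlie it and was not tested.

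The relative median of the hypoxia and glycolysis list was above 0, and that of the proliferation list below 0, in each of 6 endothelial-like sets. Medians in this paragraph count only members that a set holds at 20 CPM or more, unlike those given above. That left 10 hypoxia members in cluster 5 and 4 proliferation members in brain endothelial-like cells. Members were split for hypoxia in brain endothelial-like cells (6 above and 6 below the median gene) and for proliferation in cluster 3 (9 above and 13 below, median −0.08). If these were shifts of the whole embryo or library, sets outside the endothelium would move alike. The proliferation list was lower by more than 0.2 in 5 of 7 such sets, with neutrophil-like cells opposite at 0.50, which is consistent with a shift beyond the endothelium in most of them. The hypoxia list was higher by more than 0.2 in 4 of 7 sets, with erythroid-like cells opposite at −0.20. Epidermis-like cells, at 0.196, and neuron-like cells, at 0.190, lay just below that bound, which was chosen after the data were seen. A shift of the whole library is therefore neither met nor excluded. Missing circulation in the mutant embryos could bear on either list and was not tested.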

How the results depend on the processing

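With 1 library per group, a value counted as stable when an alternative lay within its counting interval. List medians in this part are those of cluster 5 before the median gene was subtracted, unlike the relative medians given above. The arterial list stayed within its interval in all 16 alternatives (0.17 to 0.65). The valve list did so in 15 of 16, the flow list in 15, the endocardial and lymphatic lists in 14 and the venous list in 13. Without a minimum of 2000 UMIs, which removed no cell, the endocardial-like share held in 3 of 8 alternatives in the mutant and 6 of 8 in the sibling library, and the slope in 5 of 13. Counts limit the rest, with 20 UMIs enough for a member to enter a list. The stricter filter on cells gave shares of 0 and 17.2%, medians of 0.45 for endocardial, −0.55 for venous and −0.61 for lymphatic genes, and a slope of −0.105. Clustering each library on its own gave shares of 0 and 4.58% and turned the slope to 0.0245, with 16.5% of sibling and 0.911% of mutant cells once unnamed clusters scoring highest for endocardial markers were added after seeing the data. Keeping list genes among the variable genes gave a mutant share of 0.636%. Centring each library, also added afterwards, gave 0.607% and a slope of −0.0179. Leaving out the genes that set the endocardial-like cluster apart, likewise added, gave no endocardial-like cluster, and medians of −0.44 for the endocardial, −0.53 for the valve (sign turned) and −0.29 for the flow list. The matching cells rose there from 297 to 560 in the sibling library, so these medians set other cells against each other. The venous median moved to −0.0077 with TMM and −0.0067 with median-of-ratios factors, because 1 factor shifts all genes. With no count minimum the lymphatic median was −0.17 and the slope turned to 0.00355. The slope was −0.0150 with doublets kept, −0.0243 at resolution 0.5, −0.0471 at resolution 2 and −0.0167 with thinned cells. Except for the scalings, the cause was not tested. Other scalings were not run for the slope, which 1 factor cannot move. No paired analysis was possible because each group had 1 library and no result came from a test.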

Other observations

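The test in this part of cells of endocardial origin, and the split of cluster 5 by lyve1b, were chosen only after the data had been seen.

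Brain endothelial-like cells, marked by the transporters of the blood-brain barrier, had lower levels of replication genes in the mutant library, among other differences. Vim was 20.2-fold higher in the mutant library (649.8 and 32.2 CPM, 16.0 to 25.7), uchl1 7.10-fold, cadm1b 4.88-fold, tmem97 4.06-fold and the chemokine scavenger ackr3b 3.97-fold higher. The glycerol phosphate dehydrogenase gpd1b was 49.1-fold lower (2.34 and 115 CPM, 22.3 to 135), mmel1 32.4-fold, the chemokine cxcl12b 15.6-fold, ncam3 12.9-fold and krt94 11.4-fold lower. Mitochondrial UMIs were 3.53% of mutant and 2.31% of sibling UMIs in these cells. Proliferation genes were lower for 13 of 17 members, mcm3 by 6.35-fold and mcm5 by 4.94-fold, at a relative median of −1.02 (percentile 0). Venous genes were lower for 6 of 12 and higher for 1, nr2f2 by 2.98-fold, at −0.40 (percentile 0.95). Dissociation stress genes were lower for 12 of 23, nr4a1 by 4.199-fold, at −0.35 (percentile 0).

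In the cycling cells of cluster 3, led by plk1 and top2a, the glycolytic enzyme eno1a was 3.11-fold higher in the mutant library (215 and 69.1 CPM), vim 2.93-fold, tm4sf18 2.75-fold and edn2 2.72-fold higher. Abcc2 was 7.02-fold, rhag 6.03-fold, bnc2 4.19-fold, emid1 4.103-fold and alpl 3.85-fold lower. Venous genes lay at −0.25 (percentile 0.16) and lymphatic genes at −0.23 (percentile 0.23), while proliferation genes lay at −0.08. In cluster 6, with arterial and tip markers, hmgcra was 13.6-fold higher in the mutant library (31.9 and 2.34 CPM, 5.64 to 42.7), cdaa 12.3-fold, hsd17b7 7.01-fold, cyp51 6.55-fold and vim 5.15-fold higher. Fstl1a was 15.4-fold, anxa2a 14.7-fold, tuft1a 7.73-fold, cfd 5.09-fold and ppp1r1c 5.06-fold lower there. Stress genes were lower for 12 of 23, at −0.44 (percentile 0), and lipid and scavenger genes higher for 6 of 17, at 0.43 (percentile 99.98). Mitochondrial UMIs were 2.87% of mutant and 1.96% of sibling UMIs in cluster 3, and 3.39% and 2.25% in cluster 6.

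Cells outside the endothelium made up 52.6% of mutant and 50.7% of sibling kept cells despite the sort. Neutrophil-like cells made up 15.2% and 17.3%, blood progenitor-like cells 7.66% and 10.97%, and erythroid-like cells 4.37% and 2.43%. In the epidermis-like cells hmgcra was 12.05-fold higher in the mutant library (34.3 and 2.85 CPM) and cyp51 7.85-fold higher. In mesenchyme-like cells vim was 20.4-fold higher (222 and 10.9 CPM). The neuron-like cluster held insulin transcripts at 3955 CPM in the mutant library and 0 in the sibling library, but they lay in 5 of 162 mutant and 0 of 103 sibling cells (up to 3.52%), and 1 cell held 64.5% of them. Prolactin transcripts lay in 1 cell of each library.

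A hypothesis was that mutant cells of endocardial origin lie in cluster 5 with part of their identity left. In that case, marker genes of sibling endocardial-like cells outside the lists would be higher in mutant than in sibling cluster 5. Over 118 such genes the median was 0.064 relative to the median gene (−0.01 to 0.20). It would also have to exceed the other sets. Veno-lymphatic-like cells lay at −0.18 (−0.26 to −0.06), arterial-like cells at −0.40 (−0.53 to −0.24) and brain endothelial-like cells at −0.37 (−0.48 to −0.14), below it. Cluster 3 at −0.07 (−0.19 to 0.05) and cluster 6 at −0.18 (−0.27 to 0.05) had intervals that overlapped that of cluster 5, and neutrophil-like cells lay at 0.116 (0.022 to 0.179), so the hypothesis was neither met nor excluded. Cells of cluster 5 without a lyve1b UMI held has2 in 34.7% of mutant cells (35 of 101) and 7.41% of sibling cells (6 of 81), or 24.0% and 4.08% after thinning. Cells with lyve1b held it in 9.23% and 4.63% (5.60% and 2.51% thinned). Gata5 was in 21.8% of mutant and 32.1% of sibling cells without lyve1b (14.7% and 20.4% thinned) and in 5.38% and 1.85% of cells with it (3.45% and 1.01% thinned). In neutrophil-like cells has2 was in 0 of 1014 mutant and 0.214% of sibling cells, and gata5 in 0.0986% and 0.321%.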
